A study of Mus musculus with 6 samples.

How the data were processed

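The libraries were made from total RNA of brown adipose tissue that was frozen and pulverised, from 3 mice per genotype, per the labels' protocols. The authors deposited a table of read counts per gene, with gene symbols in rows and 1 column per library, in the layout HTSeq writes. The submitters' processing notes name Trim Galore, Bowtie2 2.3.4.3, STAR 2.7.2b, SAMtools 1.9, HTSeq, edgeR and the build mm10, without saying which step each was used for. The annotation, the strand setting of the counting and the rule for reads with several matches are not given in the sources used here. Without strand, reads of overlapping genes on opposite strands would be pooled or set aside as ambiguous.

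Each library was assigned to its group by the genotype in its labels, and replicates were numbered in accession order within a group, which pairs nothing. The library titles carry a prefix, RF in 4 libraries (heterozygous 1 and 2, knockout 1 and 2) and RE in 2 (heterozygous 3 and knockout 3), whose meaning the labels do not give. The second principal component separated RE from RF (-19.4 and -54.1 against 12.9 to 27.5), so values within each prefix are given beside the pooled ones for the lists that passed, the thermogenic genes, Fam195a, Ucp1, Ppargc1a and Dio2; the RE pair has 1 library per group and no test, and its log2 ratios were taken with 0.5 CPM added. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 42 to 329).

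The 5 closing lines of the count table, which name no gene, were kept out of library sizes and tests. Reads with more than 1 alignment made up 22.9% ± 1.1 of the column total in the heterozygous-labelled libraries and 18.3% ± 1.3 in the knockout-labelled ones (SD, n = 3 each). Reads outside annotated features made up 28.6% ± 1.2 and 24.1% ± 2.6, reads not aligned 1.94% ± 0.11 and 1.95% ± 0.036, and reads of low alignment quality 0.168% ± 0.032 and 0.179% ± 0.022. Column totals ran from 40280066 to 45792698 reads. Of 24062 symbols, 6303 had no count in any library.

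Differences were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with its minimum count of 10 and minimum total of 15, which left 13300 genes, and the robust quasi-likelihood F test on genotype alone, with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 24.7%, and the median log2 fold change of all tested genes 0.02. CPM values use the TMM-scaled library sizes. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, adjusted over the 27 lists with at least 5 tested genes, and again with an estimated correlation and with fry, which tests whether the genes of a list move on balance one way. Of 30 lists, 3 were not tested: mitochondrially encoded mRNAs (0 of 13 symbols matched), lymphocyte markers (4 tested genes) and red blood cell transcripts (2 tested genes). The lists, the rule for named genes and the alternatives were fixed before the data were examined; 6 further lists of mitochondrial genes and 2 fits with a muscle score as a covariate were chosen afterwards.

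Named genes were the targeted gene; up to 10 genes in each direction with the largest change among those called, with non-overlapping groups and an average log2 CPM of at least 1; in each list up to 4 called members with the smallest adjusted p, and in lists that passed or held no call up to 4 members with the smallest p; and always Ucp1, Ppargc1a, Dio2, Bckdha, Bckdhb, Bcat2 and Slc25a44. Of the 78 called genes, 76 met both conditions. Predicted genes were counted but not described, and some genes that the rule picks are not reported here.

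Symbols were placed on GRCm38, the assembly mm10 names, with GENCODE release M21: 22750 of the 24062 symbols matched directly, 916 through 1 older symbol, and 396 were unmatched. This annotation may differ from the one used for counting, and gave only coordinates, transcript length and GC content.

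The test was tried on simulated counts for the 13300 genes of this comparison, with 200 genes changed. It recovered 39% of 100 genes changed by 1 on the log2 scale and 93% of 100 changed by 2, and 10 of its 142 calls (7.04%) were false. A simulated list of 25 genes lowered by 1 had an adjusted p of 2.06e-41, and an unchanged list 0.904. The simulated genes varied independently, so these 2 lists cannot show how camera at its preset correlation behaves for correlated genes. The estimated correlation was 0.498 for branched-chain amino acid catabolism and 0.927 for skeletal muscle markers.

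Alternatives were RLE scaling, library size only, no filter on low counts, a mean CPM of at least 1, each library left out in turn, the title prefix as a covariate, the RF-titled libraries alone, DESeq2 1.42.0, limma-voom with quality weights, no robust estimation, an adjusted p of 0.1, muscle genes left out of the library sizes, and the other list tests. Mitochondrially encoded genes were to be left out of the library sizes too, but none was matched. P-values of the tests per gene rest on the spread between mice of one labelled genotype. Camera at its preset correlation treats the genes of a list as nearly independent. The p-values over random gene lists, of the correlation with transcript length and of Fisher's exact test are taken across genes, not mice.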

Results

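Brown adipose tissue, the fat depot that burns fuel to make heat, was profiled by RNA sequencing in male C57BL/6 mice aged 12 weeks. The series concerns FAM195A, described there as an RNA-binding protein of stress granules needed for heat production in the cold. The tissue came from 3 mice labelled heterozygous for FAM195A and 3 mice labelled knockout, and the temperature at which they were kept is not given in the sources used here. The comparison asks which transcripts differ in this tissue when both copies of the gene are disrupted rather than 1. The reads counted in genes came to 18781401, 19825537 and 20471963 in heterozygous 1, 2 and 3, and to 22418031, 25084627 and 23373773 in knockout 1, 2 and 3. Genes held 46% ± 2.2 (SD, n = 3) of the column totals in the heterozygous-labelled libraries and 55% ± 3.7 (SD, n = 3) in the knockout-labelled ones, with all 3 knockout-labelled libraries above all 3 others (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows).

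The targeted gene did not pass the threshold. Fam195a, named Mcrip2 in newer annotation, lies on the minus strand of chromosome 17 from 25863698 to 25868764 (GRCm38). It is inside the span of the long noncoding RNA gene Gm26694 on the plus strand. Reads of the pair from the same stretch cannot be told apart unless strand was used in counting. Whether exons of the 2 genes overlap was not examined. Its level was 80.8 ± 19.1 CPM (read count scaled to a common library size) in the heterozygous-labelled libraries and 71.3 ± 18.0 in the knockout-labelled ones (SD, n = 3 each). Fam195a stood at 69.0, 70.5 and 103 CPM in heterozygous 1, 2 and 3, and at 50.5, 82.0 and 81.3 CPM in knockout 1, 2 and 3. The log2 fold change was -0.18 (SE 0.241, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.896), with a 95% interval of -0.745 to 0.384, or 59.7% to 131% of the heterozygous-labelled level. A partial loss is therefore not excluded. The log2 fold change was -0.08 within the RF-titled libraries and -0.34 in the RE-titled pair. A count per gene does not show which exons the reads came from. Because this transcript does not bear out the labels, every direction below is that of the libraries labelled knockout relative to those labelled heterozygous.

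**Figure D1:**
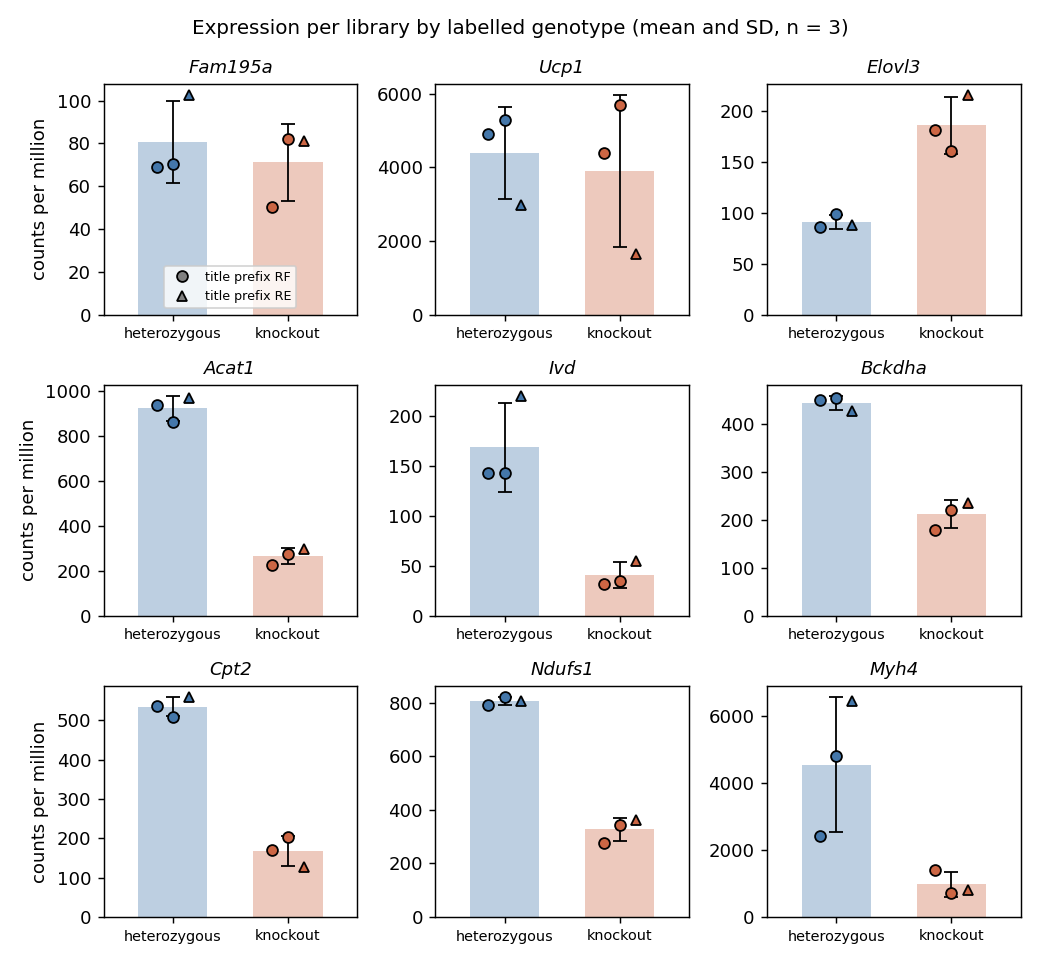
CPM, the read count scaled to a common library size (vertical axes, starting at 0), of 9 genes in each library, with bars for the mean and error bars for the SD of the 3 libraries per labelled genotype; circles carry the title prefix RF and triangles RE. Fam195a spans overlapping ranges in the 2 groups (69.0 to 103 and 50.5 to 82.0 CPM), whereas Acat1 stands at 923 CPM in the heterozygous-labelled libraries and 265 CPM in the knockout-labelled ones.

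Lists of branched-chain amino acid catabolism, fatty acid oxidation and the tricarboxylic acid cycle were lower in the knockout-labelled libraries by camera at its preset correlation, but did not pass with an estimated correlation (adjusted p = 0.278, 0.278 and 0.325). Among the metabolic lists the first had the lowest median, -1.10, while skeletal muscle markers, at -2.22, moved the same way. Of 13300 genes tested, 71 fell and 7 rose at an adjusted p of 0.05, by 1.66-fold to 13.8-fold. In all 78 the 3 knockout-labelled libraries lay on one side of the 3 others; 18% of all tested genes did so, against 10% by chance. Among the called genes, 19 belonged to the 4 lists of branched-chain amino acid catabolism, fatty acid oxidation, the tricarboxylic acid cycle and nuclear respiratory chain subunits. These lists hold 146 of the 13300 genes tested, and the respiratory list gave 1 of the calls.

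Among the genes that rose with an average log2 CPM of at least 1, the largest changes were in Cbr3, a carbonyl reductase (log2 fold change 2.07, SE 0.292, adjusted p = 0.0388), and Anxa4, a calcium-dependent phospholipid-binding annexin, which went from 9.04 ± 1.42 to 35.4 ± 2.4 CPM (log2 1.97, SE 0.164, adjusted p = 0.0152). Nudt4, a diphosphoinositol polyphosphate phosphatase (log2 1.14), Elovl3, a fatty acid elongase abundant in brown fat (1.03), the collagen gene Col27a1 (0.98) and Tmem79 (0.95) also rose. Among those that fell at that level, Rnaset2b showed the largest change (log2 -3.59; 4.07 ± 0.41 against 0.335 ± 0.11 CPM), which is uncertain because the near-identical copy Rnaset2a can share its reads. Ppp1r14c, an inhibitor subunit of protein phosphatase 1, fell by 2.10 on the log2 scale, and Chdh, the mitochondrial choline dehydrogenase, fell by 1.79. Fam185a fell by 1.61. Cox15, which makes heme A for cytochrome oxidase, fell from 67.0 ± 4.63 to 22.4 ± 2.22 CPM (log2 -1.58, SE 0.134, adjusted p = 0.0152).

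In branched-chain amino acid catabolism, the mitochondrial breakdown of leucine, isoleucine and valine, 26 of 28 tested genes had log2 fold changes below 0. Of these 28 genes, 10 fell and none rose over all genes tested, and 22 fell and 2 rose when adjusted over the list alone. The count of 10 was 16 without knockout 3, 3 without heterozygous 3 and 0 without heterozygous 2, knockout 1 or knockout 2. It was 19 with the title prefix as a covariate and 20 by DESeq2. The median log2 fold change was -1.10 (camera adjusted p = 2.02e-37; adjusted p = 0.278 with an estimated correlation; fry adjusted p = 0.0467). Ivd, isovaleryl-CoA dehydrogenase of leucine breakdown, went from 168 ± 44.6 to 40.7 ± 12.7 CPM (log2 -2.05, SE 0.276, adjusted p = 0.0367). Acat1, the mitochondrial acetoacetyl-CoA thiolase, went from 923 ± 55.2 to 265 ± 36.1 CPM (log2 -1.80, SE 0.159, adjusted p = 0.0152). The carboxylase subunits Mccc1 (log2 -1.49), Pcca (-1.41) and Pccb (-1.53), the dehydrogenase Acad8 (-1.22) and Bckdha (-1.07, adjusted p = 0.0367), a subunit of the branched-chain ketoacid dehydrogenase, fell too. Its partner subunit Bckdhb did not pass (log2 -0.35, adjusted p = 0.33), nor did the mitochondrial aminotransferase Bcat2 (-1.52, adjusted p = 0.251; -0.89 without heterozygous 3) or Slc25a44, the mitochondrial carrier of branched-chain amino acids (0.56, adjusted p = 0.273). The list median was -1.13 within the RF-titled libraries (2 against 2) and -0.843 in the RE-titled pair (1 against 1, no test).

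**Figure D2:**
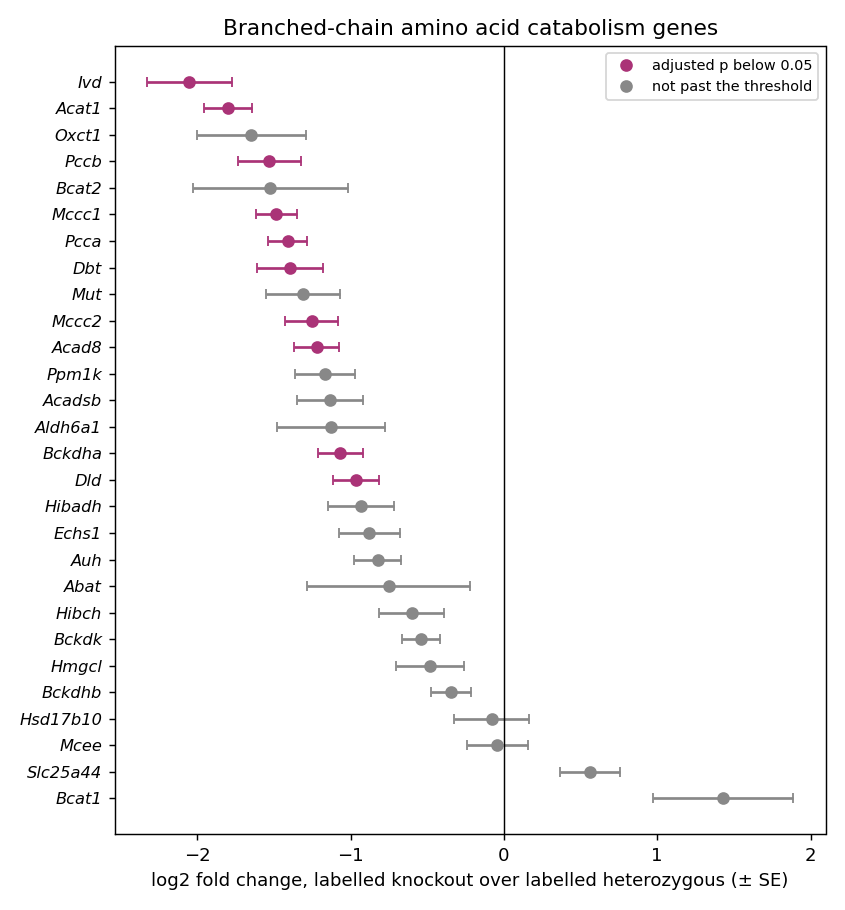
Log2 fold change (horizontal axis, libraries labelled knockout over those labelled heterozygous, n = 3 each) of the 28 tested genes of branched-chain amino acid catabolism, with bars of 1 SE and the genes past an adjusted p of 0.05 in purple. The list median is -1.10, and 26 of the 28 genes lie below 0.

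The tricarboxylic acid cycle and fatty acid oxidation lists were lower as well. In the cycle, 4 of 22 tested genes fell and 13 fell when adjusted over the list alone, with a median of -0.60 (camera adjusted p = 2.14e-18; adjusted p = 0.325 with an estimated correlation). They were Suclg2, a succinyl-CoA ligase subunit (log2 -1.60), the isocitrate dehydrogenase subunits Idh3g (-1.16) and Idh3b (-1.08), and Dld (-0.97), which the list shares with branched-chain amino acid catabolism. In fatty acid oxidation, 5 of 26 genes fell, and 13 fell and 1 rose when adjusted over the list alone, with a median of -0.62 (camera adjusted p = 2.94e-15; adjusted p = 0.278 with an estimated correlation). Cpt2, the inner carnitine palmitoyltransferase, went from 535 ± 24.8 to 167 ± 38.3 CPM (log2 -1.68, adjusted p = 0.0248), and Etfdh, which passes electrons from fatty acid oxidation to ubiquinone, from 970 ± 93.8 to 342 ± 33.1 CPM (log2 -1.50). Acads (-1.26) also fell, as did Acot2 (-1.43), whose reads may be split with its close paralogs. Within the RF-titled libraries the medians were -0.731 for the cycle and -0.71 for fatty acid oxidation, and in the RE-titled pair -0.352 and -0.551.

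Respiratory chain subunits and thermogenic genes did not pass as lists moving one way. Both passed by fry for members changing in either direction (adjusted p = 0.00339 and 0.0462). Of 75 nuclear-encoded respiratory subunits, 1 fell and 6 fell when adjusted over the list alone. The median was 0.16, the mean -0.00226 and the test's direction up (camera adjusted p = 0.646). With a muscle score, described below, as a covariate the list passed as lower (median -0.136, adjusted p = 0.000156; adjusted p = 0.994 with an estimated correlation). The gene that fell was Ndufs1, a core subunit of complex I (log2 -1.31, SE 0.152, adjusted p = 0.0254). Of 30 thermogenic genes, Elovl3 alone passed and rose, 2 rose when adjusted over the list alone, and the list median of -0.08 differed in sign from its mean of 0.091 and from the test's direction, up (camera adjusted p = 0.646). Ucp1, the uncoupling protein that releases heat, stood at 4384 ± 1250 and 3910 ± 2070 CPM (SD, n = 3 each; log2 -0.16, SE 0.448, adjusted p = 0.958). Ppargc1a, a coactivator of mitochondrial biogenesis (-0.79, SE 0.709, adjusted p = 0.805), and Dio2, which activates thyroid hormone (-0.70, SE 0.7, adjusted p = 0.835), did not pass. Leaving out single libraries moved Ucp1 between -0.54 (without knockout 2) and 0.19 (without knockout 3). It moved Ppargc1a between -1.24 (without heterozygous 3) and -0.38 (without knockout 3), and Dio2 between -1.18 (without heterozygous 3) and -0.29 (without heterozygous 2). Within the RF-titled libraries and in the RE-titled pair, Ucp1 was at -0.02 and -0.85, Ppargc1a at -0.83 and -0.44, Dio2 at -0.82 and 0.28, and the thermogenic median -0.00764 and 0.077.

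Lipid synthesis lists were higher by the list test, with no single gene past the threshold over all genes tested. All 20 de novo lipogenesis genes had log2 fold changes above 0, with a median of 0.53 (camera adjusted p = 2.09e-08; adjusted p = 0.452 with an estimated correlation), and 1 rose when adjusted over the list alone. The fatty acid desaturase Scd2 stood at 505 ± 159 and 1905 ± 540 CPM (log2 1.92, SE 0.322, adjusted p = 0.0593), and Acly, which makes cytosolic acetyl-CoA, had a log2 fold change of 0.87 (adjusted p = 0.408). For 23 cholesterol synthesis genes the median was 0.43 (camera adjusted p = 2.09e-07; adjusted p = 0.452 with an estimated correlation), and 3 rose when adjusted over the list alone. Insig1 (log2 1.04, adjusted p = 0.0719), Sqle (1.35, adjusted p = 0.0892) and Mvd (1.10, adjusted p = 0.0805) had the smallest p of that list. The RF-titled medians were 0.355 and 0.245 and the RE-titled pair's 1.17 and 0.981 for lipogenesis and cholesterol synthesis. The cholesterol median was 0.68 without heterozygous 1, 0.24 without heterozygous 3 and 0.28 without knockout 1, and the call held in each. With the muscle score described below as a covariate neither list passed: the medians were 0.065 for lipogenesis (adjusted p = 0.984) and 0.083 for cholesterol synthesis (adjusted p = 0.488).

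Skeletal muscle transcripts were lower in the knockout-labelled libraries and varied within both groups. All 26 muscle genes had counts in every library and log2 fold changes below 0; none passed over all genes tested by edgeR, and all 26 fell when adjusted over the list alone. Of the 26, 22 fell by DESeq2, 22 without heterozygous 1 and 21 at an adjusted p of 0.1. Their median was -2.22 (camera adjusted p = 1.97e-45; adjusted p = 0.278 with an estimated correlation), with -1.72 within the RF-titled libraries and -3.12 in the RE-titled pair. Myh4, a fast muscle myosin, stood at 2427, 4796 and 6446 CPM in heterozygous 1, 2 and 3 and at 1403, 709 and 811 CPM in knockout 1, 2 and 3 (log2 -2.23, SE 0.42, adjusted p = 0.0736). Neb (-2.73, adjusted p = 0.0715), Myh2 (-2.88) and Casq1 (-2.17) had similar adjusted p values. The muscle score, the mean log2 CPM of these genes, was 8.03, 9.41 and 9.74 in the heterozygous-labelled libraries and 7.43, 6.69 and 6.27 in the knockout-labelled ones, and so moved with the genotype label as the fuel oxidation lists did.

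Creatine and calcium cycling, a list of heat-producing cycles that do not need Ucp1, had a median of -0.66 over 10 genes (camera adjusted p = 0.00174; adjusted p = 0.502 with an estimated correlation), with no gene past the threshold and 5 lower and 1 higher when adjusted over the list alone. Its leading members Ryr1 (log2 -2.53), Atp2a1 (-2.29), Ckmt2 (-2.44) and Sln (-2.85) are also abundant in skeletal muscle, and Atp2a1 is on both lists. That median was -0.29 without heterozygous 3, where the call held, and -0.24 in the RF-titled libraries (adjusted p = 0.139), against -1.18 in the RE-titled pair. With the muscle score the call was lost and the median changed sign (0.108, adjusted p = 0.46). In the cytosolic heat shock list (18 genes, median -0.13, camera adjusted p = 0.0232; adjusted p = 0.628 with an estimated correlation), only Hspd1 fell (log2 -1.06, adjusted p = 0.0427), a chaperonin that works in mitochondria. The muscle-rich small heat shock genes Hspb6 (-2.14, adjusted p = 0.0719) and Cryab (-2.15, adjusted p = 0.0736) followed. When adjusted over the list alone, 3 fell. The heat shock call was lost without heterozygous 2 (median 0.08, adjusted p = 0.338), without knockout 3 (-0.02, adjusted p = 0.526) and with the muscle score (-0.24, adjusted p = 0.488). It held without the other libraries, at medians of -0.06 without heterozygous 1, -0.27 without heterozygous 3, -0.32 without knockout 1 and -0.22 without knockout 2. The median was -0.146 in the RF-titled libraries and -0.105 in the RE-titled pair.

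The interferon response list (24 genes, median 0.28, camera adjusted p = 0.00239; adjusted p = 0.628 with an estimated correlation) and the integrated stress response list (20 genes, median 0.28, camera adjusted p = 0.0404; adjusted p = 0.348 with an estimated correlation) were higher by the list test, and none of their genes passed over all genes tested. Adjusted over the list alone, none of the interferon genes passed and 1 stress response gene fell. Gbp2 had a log2 fold change of 0.36 (adjusted p = 0.341), Atf4, the transcription factor of the stress response, 0.56 (adjusted p = 0.242), Trib3 0.90 and Mthfd2 1.58, whereas Shmt2 was at -0.61 (adjusted p = 0.0829). The interferon call was lost without heterozygous 2 (median 0.19, adjusted p = 0.139) and without knockout 1 (0.15, adjusted p = 0.0785). The stress response call was lost without heterozygous 1 (0.19, adjusted p = 0.173), knockout 2 (0.31, adjusted p = 0.133) or knockout 3 (0.16, adjusted p = 0.0619). With the muscle score both calls held, at medians of 0.406 for interferon (camera adjusted p = 0.00136) and 0.417 for the stress response (camera adjusted p = 0.0295). Neither held with the score and an estimated correlation (camera adjusted p = 0.994 and 0.419). The RF-titled and RE-titled medians were 0.387 and 0.112 for interferon and 0.277 and 0.355 for the stress response.

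**Figure D3:**
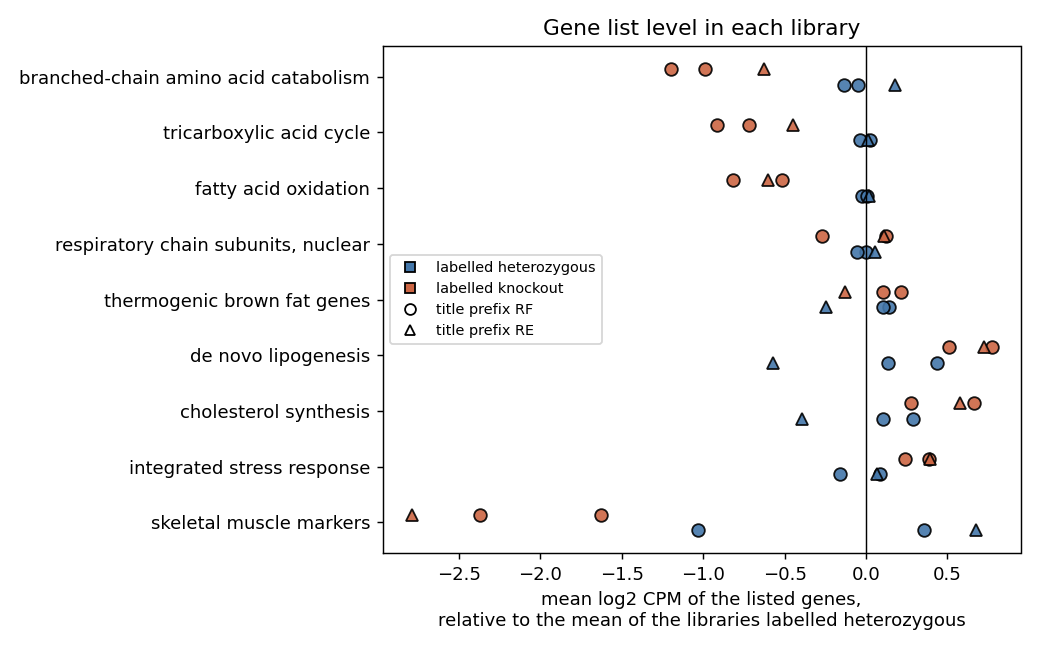
Mean log2 CPM of the genes of 9 lists in each library (horizontal axis), relative to the mean of the 3 libraries labelled heterozygous; blue marks libraries labelled heterozygous, orange those labelled knockout, circles the title prefix RF and triangles RE. For branched-chain amino acid catabolism the knockout-labelled libraries lie at -1.2, -0.991 and -0.624 and the others between -0.133 and 0.18.

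The other lists did not pass and held no gene past the threshold over all genes tested. Among metabolic and stress lists, the medians and camera adjusted p were 0.29 and 0.257 for glycolysis (Pfkfb3 at -1.02, adjusted p = 0.105), 0.06 and 0.555 for lipid uptake, 0.27 and 0.134 for immediate early genes, 0.04 and 0.578 for endoplasmic reticulum chaperones, 0.04 and 0.435 for ribosomal proteins, -0.11 and 0.646 for the circadian clock and -0.09 and 0.994 for the cell cycle. With the muscle score the circadian clock list passed as lower (median -0.53, adjusted p = 0.0116; adjusted p = 0.749 with an estimated correlation). Median and test differed in sign for lipolysis (-0.003, up, 0.435), white adipocyte markers (-0.05, up, 0.435) and stress granule proteins (-0.02, up, 0.646). Among cell type markers, the values were 0.10 and 0.173 for endothelium, 0.17 and 0.27 for macrophages, 0.04 and 0.435 for fibroblasts, -0.08 and 0.255 for smooth muscle and pericytes (Des, also abundant in skeletal muscle, at -1.68, adjusted p = 0.081) and -0.21 and 0.978 for Schwann cells. Adjusted over the list alone, 1 gene fell in the lipolysis list and 1 in the smooth muscle list, and none passed in the other lists of this paragraph.

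The count of 78 genes rested on single libraries. It was 400 without heterozygous 1, 8 without heterozygous 3 and 111 without knockout 3. It was 0 without heterozygous 2, knockout 1 or knockout 2, where 1257, 1450 and 1393 genes had an unadjusted p under 0.05. All 78 genes kept their direction in each of these fits, but groups that do not overlap leave little room for another outcome. The count was 132 within the RF-titled libraries and 311 with the title prefix as a covariate, 755 by DESeq2 and 194 by limma-voom. It was 0 with the muscle score as a covariate (286 at an unadjusted p under 0.05). None of the 10 list calls held with an estimated correlation.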

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

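The tests of the muscle score, of the respiratory chain subunits, of the correlation among muscle genes and both tests on Fam195a were chosen only after the results they bear on were seen. The rules for reading the first 3 of them were also changed after their results were seen, which altered the verdict on muscle as the cause of the branched-chain difference 2 times and that on adjoining muscle once.

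Reads that fell on more than 1 gene, which enter no comparison, made up 0.441% ± 0.063 of the column totals in the libraries labelled knockout and 0.34% ± 0.014 in those labelled heterozygous (SD, n = 3 each), and all 3 knockout-labelled libraries lay above the others.

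Fam195a was not called lower in the libraries labelled knockout. If libraries had been exchanged between the groups and the allele removed the transcript, at least 1 library should hold little of it. The same holds for such an allele without an exchange. The lowest library stood at 66.5% of the median of the 6. That argues against an allele that removes the transcript, unless reads of the overlapping Gm26694 were counted in, but says nothing on an exchange as such. An allele that leaves most of the transcript in place may account for the log2 fold change of -0.18, yet a count per gene cannot show a disrupted exon, so this stays open. An exchange of libraries with an allele that leaves the transcript in place was not tested. A wrong label of another kind was not tested, nor was a biological explanation.

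Branched-chain amino acid catabolism genes had a median log2 fold change of -1.10. Bias from transcript length, GC content or expression is argued against by 10000 random lists matched on all 3. Their medians centred on 0.043 and reached no lower than -0.195 (percentile p over these lists = 1e-04, the smallest they can give). That p is over unrelated genes and overstates the evidence, as the list itself reached -0.564 in another split of the libraries. A general loss of mitochondrial transcripts that includes the respiratory subunits, as the whole cause, is argued against by those subunits. Their level per library differed by -0.01 between the groups (95% interval -0.378 to 0.358), above the -0.469 that is 50% of the difference in the branched-chain list. Other mitochondrial lists were lower too. Mean log2 fold changes were -0.683 for the tricarboxylic acid cycle and -0.604 for fatty acid oxidation, beside -0.914 for branched-chain catabolism. Mitochondrially encoded mRNAs were not tested. A wider loss that spares the respiratory subunits therefore stays open. With score and prefix as covariates the subunits passed as lower (median -0.159, adjusted p = 4.85e-05), but not with an estimated correlation (adjusted p = 0.993). Their level then gave an interval of -1.47 to 0.975, and the branched-chain level fell by 0.941 more than theirs (-1.68 to -0.201). With the score alone that last interval was -1.87 to 0.0584 and decides nothing, so a smaller general loss stays open. Less skeletal muscle as the whole cause is argued against only by a fit let in after the score alone had decided nothing. It regressed the list's level per library on group, muscle score and title prefix, on 2 residual degrees of freedom. The group difference was -1.19 (95% interval -1.71 to -0.667). Its slope interval of -0.314 to 0.0915 leaves out the 0.415 at which muscle would give the whole difference. With the score alone the group interval of -2.54 to 0.274 and the slope interval of -0.631 to 0.458 decide nothing. In the fits per gene the list median was -1.19 with the score (median SE 0.45, against 0.2 without it), where all 10 gene calls were lost, and -1.29 with score and prefix (median SE 0.26), where 5 genes of the list were called; with an estimated correlation the list missed the threshold in both (adjusted p = 0.366 and 0.263). Because the deciding fit was picked after results were seen, it does not settle whether muscle gave the whole difference. Muscle as part of the difference stays open, and a biological effect of genotype may contribute.

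Skeletal muscle genes had a median log2 fold change of -2.22. Differing amounts of adjoining muscle in the dissected tissue cannot be told apart from regulation of these genes in the tissue. Their deviations from the group means had a mean pairwise correlation of 0.885, against at most 0.328 over 1000 random lists of expressed genes. But the respiratory subunits reached 0.8 and the cytosolic ribosomal proteins 0.79, so such a correlation does not by itself mark a dissection effect. The muscle score spanned 3.27-fold among the heterozygous-labelled libraries alone, and the muscle myosin Myh4 reached 6446 CPM in heterozygous 3. All 26 muscle genes were detected in every library, and counts from the whole tissue cannot separate expression in brown fat from that in adjoining muscle. An effect of genotype on muscle genes was not tested and stays open.

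The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. The real split gave 78 genes, 7 higher and 71 lower, and was the only 1 of the 10 to give as many in each case; the highest other count was 0. For gene lists past the threshold at the preset correlation, 7 of the 10 splits gave at least the 10 of the real split, and the highest other gave 15. The branched-chain list had a median of -1.10 in the real split, and the largest in size among the others was -0.564.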

How the results depend on the processing

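The fits with the muscle score as a covariate were chosen only after the results were seen. All 78 called genes kept their direction in every fit listed here. Outside the fits with the muscle score, that follows almost wholly from their non-overlapping groups. In the fits with the score it gives no independent support either, as the genes were picked in the same libraries. The branched-chain amino acid list kept a median of -1.29 to -0.94. The count of 78 genes stayed within 1.5 times under RLE scaling (73), library size only (101), no filter (109, with 13 higher), a mean CPM of at least 1 (78), no robust estimation (75) and muscle genes left out of library sizes (71). Without single libraries it ranged from 0 to 400 (0 to 19 higher, 0 to 381 lower), where fewer samples were fitted, and the higher count without knockout 3 was 13. It was 311 with the title prefix as a covariate (67 higher, 244 lower), 132 in the RF-titled libraries (19 and 113), 500 at an adjusted p of 0.1 (60 and 440), 755 by DESeq2 (117 and 638) and 194 by limma-voom (29 and 165). With the muscle score it was 0 (0 higher, 0 lower; DESeq2 and limma-voom were not run with it), and with score and prefix 14 (2 and 12). The 71 lower genes had a median log2 fold change of -1.18 with a median SE of 0.14, which became -1.31 and 0.31 with the score. Of the 10 called gene lists, 0 held with an estimated correlation (branched-chain list at a median of -1.10, adjusted p = 0.278), 3 by fry, 8 to 10 without single libraries and 5 with the muscle score, alone or with the prefix. Counting all 27 lists tested, 8 to 14 passed without single libraries and 7 with the muscle score, among them respiratory subunits and the circadian clock (-0.529, adjusted p = 0.0116). With the score and an estimated correlation no list passed (lowest adjusted p = 0.366). The cause of the changes in direction below was not tested.

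Without single libraries, log2 fold changes ranged from -0.29 to 0.033 for Fam195a, -0.54 to 0.19 for Ucp1, -0.59 to 2.69 for Fosb, -0.0401 to 1 for Hoxc8, -0.77 to 2.22 for Lep and -0.03 to 0.52 for Mfap5. List medians ranged from -0.106 to -0.038 for thermogenic genes, whose test changed direction, 0.075 to 0.285 for respiratory subunits, -0.36 to 0.50 for white adipocyte markers, -0.082 to 0.042 for stress granule proteins, -0.068 to 0.128 for endoplasmic reticulum chaperones, -0.044 to 0.140 for ribosomal proteins, -0.518 to 0.054 for the circadian clock, -0.251 to 0.089 for the cell cycle, -0.055 to 0.472 for macrophages and -0.315 to 0.145 for Schwann cells.

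The list test also changed direction for the cell cycle with library size only (median -0.138), no filter (-0.086) and a mean CPM of at least 1 (-0.036, with Schwann cells at -0.199), and for thermogenic genes with the title prefix (-0.0773). In the RF-titled libraries it did so for thermogenic genes (-0.0076), respiratory subunits (0.123), stress granule proteins (-0.104) and the cell cycle (0.084), and Hoxc8 was at -0.042.

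With the muscle score, these lists changed direction: thermogenic genes (-0.068), respiratory subunits (-0.136, adjusted p = 0.000156, but 0.994 with an estimated correlation), de novo lipogenesis (0.065), creatine and calcium cycling (0.108), stress granule proteins (-0.055), endoplasmic reticulum chaperones (-0.045), ribosomal proteins (-0.061), immediate early genes (-0.249), cell cycle (0.045), fibroblasts (-0.074), smooth muscle (0.016) and Schwann cells (0.312). The genes that did, none past the threshold, were Abcc9 (0.0043), Aldoc (-0.30), Bub1b (-0.91), Ckmt2 (0.12), Dnajb11 (-0.032), Egr1 (-0.39), Fosb (-1.33), Hoxc8 (-0.42), Pfkm (0.14), Prx (1.37), Rpl38 (-0.028), Sdf2l1 (-0.021) and Sln (0.098).

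With score and prefix, the lists were thermogenic genes (-0.026), respiratory subunits (-0.159, adjusted p = 4.85e-05, but 0.993 with an estimated correlation), de novo lipogenesis (0.103), lipolysis (-0.097), creatine and calcium cycling (0.043), endoplasmic reticulum chaperones (0.0062), ribosomal proteins (-0.101), immediate early genes (-0.45), cell cycle (0.075), fibroblasts (-0.143), smooth muscle (0.068) and Schwann cells (0.2355). The genes were Abcc9 (0.00387), Aldoc (-0.29), Bub1b (-0.91), Ckmt2 (0.12), Dnajb11 (-0.0036), Egr1 (-0.59), Fosb (-1.805), Hoxc8 (-0.52), Mfap5 (-0.016), Pfkm (0.062), Prx (1.15), Rpl38 (-0.047) and Ucp1 (0.14), none past the threshold. With 3 libraries per group and the spread between libraries seen here, the simulation recovered 39% of genes changed by 1 on the log2 scale. Smaller changes would therefore mostly be missed.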

Other observations

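The 6 mitochondrial lists below and their tests were chosen only after the results were seen, and the rule for reading how many of them were lower was changed after its result was seen, which altered its verdict.

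Of 6 lists of genes that build and maintain mitochondrial proteins, 4 were lower in the libraries labelled knockout with an estimated correlation. The adjusted p of these lists was taken over the 6 alone, not over the 27 lists fixed beforehand, so the values do not compare. The lists were written with the called genes in view, so their p-values give no independent support. Of 17 mitochondrial aminoacyl-tRNA synthetases, which charge tRNAs inside the organelle, 3 fell (median log2 -0.72; adjusted p = 0.0178 with an estimated correlation), among them Iars2 (log2 -1.32, edgeR Benjamini-Hochberg adjusted p = 0.0185). Of 26 mitochondrial translation and RNA factors 7 fell (median -0.48; adjusted p = 0.0178 with an estimated correlation), with the elongation factor Gfm1 at -1.37 and the polyribonucleotide nucleotidyltransferase Pnpt1 at -1.27. Of 24 mitochondrial chaperones, peptidases and import factors 8 fell (median -0.63; adjusted p = 0.0199 with an estimated correlation), with the processing peptidase Pmpcb at -1.27 and Immt, an organiser of the inner membrane folds, at -1.13. Of 11 coenzyme Q synthesis genes 3 fell (median -0.56; adjusted p = 0.028 with an estimated correlation), including Pdss2 at -1.31. Respiratory chain assembly factors (6 of 29 fell, median -0.23; adjusted p = 0.0507 with an estimated correlation) and mitochondrial ribosomal proteins (4 of 76 fell, median -0.08; adjusted p = 0.514 with an estimated correlation) did not pass with an estimated correlation. Genes in this paragraph were named after their values were seen.

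The hypothesis that these groups fall together with amino acid catabolism was not settled: 6 of the 6 lists were lower at the preset correlation, but 3 of the other 9 splits of the libraries also moved all 6 one way. The lists were written after the calls were seen, and hold 30 called genes outside the 4 fixed mitochondrial lists. With the muscle score as a covariate no gene was called. The median SE of the 71 lower calls went from 0.14 to 0.31, their median log2 fold change from -1.18 to -1.31, and all 71 stayed below 0. These 71 genes were picked as lower in the same 6 libraries, and the score itself separates the groups. Their kept direction therefore gives no independent support. With score and prefix 5 of the 78 calls were shared. The medians with the score were -0.846 for the synthetases (adjusted p = 0.0369 with an estimated correlation), -0.683 for translation and RNA factors (adjusted p = 0.0369), -0.696 for chaperones, peptidases and import (adjusted p = 0.0369), -0.607 for coenzyme Q synthesis (adjusted p = 0.0441), -0.507 for assembly factors (adjusted p = 0.043) and -0.184 for ribosomal proteins (adjusted p = 0.329). With score and prefix the lowest of these adjusted p was 0.116.

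Within the respiratory chain list, longer transcripts may have fallen more: across its 75 genes the Spearman correlation of log2 fold change with transcript length was -0.417 (permutation p = 4e-04; genes are not independent replicates). Across 12890 tested genes outside the mitochondrial lists it was -0.161, and -0.0989 across the 1398 of them in the same range of expression and length, so a length trend over all genes cannot be told apart as part of it: -0.161 lies between the bounds set for and against, and -0.0989 just past the bound against.

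A segment around Fam195a that differs between the genotypes could place called genes near it: 0 of 314 tested genes within 10 Mb were called, against 78 elsewhere (odds ratio 0, 95% interval up to 1.99, Fisher's exact two-sided p = 0.267), too few to decide. The called gene Rnaset2b lies on the same chromosome, 17, from 6970634 to 7011299, outside this window. A longer segment was not tested.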
